A study of Mus musculus with 2 samples.

How the data were processed

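The data were 2 microarrays (Affymetrix Mouse Gene ST, whole-transcript) of RNA from sorted mTEC of the labelled genotypes WT and HDAC3cKO, 1 array each. Per the labels' protocols, thymi were digested enzymatically, stroma was enriched on a Percoll gradient, and cells were sorted straight into Trizol, after which total RNA was amplified and biotin-labelled cRNA was hybridized. The deposited table held one intensity per probe set and array on a linear scale, from 10.8 to 29745 on the array labelled WT and from 11.5 to 29465 on the array labelled HDAC3cKO. Per the submitters' processing notes the values come from RMA, a method that corrects background, normalizes across arrays and summarises the probes of each probe set. Its version, its settings and the arrays that entered the normalization are not given in the sources used here. The sorted values of the 2 columns were not identical. Log2 values had been assumed before the data were examined, and the linear intensities were therefore transformed to log2 with no pseudocount and no further scaling. The table holds no detection calls, so a low level cannot be read as absence, and a fold against a level near background understates the difference.

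Probe sets were named through the platform annotation, which can be old, and symbols were looked up by Entrez identifier in a RefSeq gene table of GRCm38.p6. Of 34760 probe sets, 21640 had 1 gene symbol, 1321 had several and were not named, and 11799, control probe sets possibly among them, were unnamed here. Of those with 1 symbol, 21553 matched the gene table, with no symbol changed, and 87 kept the annotation's symbol. No genome build is named for the values, so no coordinates are given. For the 954 genes with more than 1 probe set, the one with the highest mean over both arrays was used, giving 19937 genes. The level of each array correlated across genes with r = 0.945 on the log2 scale. Genes are not independent replicates. The median gene difference was 0.01, and the central 95% of genes lay between -1.72 and 1.07.

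With 1 array per group there is no replicate check, so no test, standard error or p-value is given. Genes were counted when their log2 difference was at least 1 or at most -1, that is 2-fold, among the 9969 genes whose mean over both arrays was at or above the median of all genes, 8.03. For 34 gene lists fixed before the data were examined (epithelial subsets, pathways, and markers of other cell types), the median difference over all measured members was set beside the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile is a description of these 2 arrays and not a significance level, and a list is said to stand apart outside the central 95%. The lists hold 620 different genes, of which 563 were measured here under a probe set of their own, 5 of them matched through an older name, and 26 sit in more than 1 list. The genes named in the text follow a rule fixed in advance. They are Hdac3, the 12 genes with the largest positive and the 12 with the largest negative difference above the filter (leaving out predicted gene models, small RNAs and olfactory and vomeronasal receptors), up to 2 members each way with a difference of at least 2-fold in each list, and 26 genes named whatever their values, of which Ccl21a was not analysed here. Pou2f3, Ivl, the class II genes, Ciita, Cd86, Ctss, Ccl6, Ccl9, Spib, Lyz2 and Tff3 were chosen after their values were seen. So were the genes named only in the closing section.

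The counts, list percentiles and rescalings were tested on simulated data with the means of the real genes, a noise SD of 0.3 chosen for the test, and 200 changed genes among 19937. Of 100 genes raised by 1.5 on the log2 scale, 92% passed the 2-fold threshold, as did 100% of 50 genes lowered by 1.5 and 0.117% of unchanged genes. Of 100 lists of 20 genes raised by 0.5, 100% lay above the 97.5th percentile, and of 100 unchanged lists 9% lay outside the central 95%. The simulated noise was independent between genes, whereas the central 95% of real gene differences ran from -1.72 to 1.07. The noise of these 2 arrays could not be measured, so these rates need not hold for them. The alternatives were median centring, quantile normalization, an intensity-dependent loess curve (span 0.3), averaging probe sets, other filters and thresholds, every probe set counted, list means, members above the filter and unmatched random lists. Leaving out members held by another list was added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.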

Results

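Gene expression was profiled in medullary thymic epithelial cells (mTEC) of mice aged 6 weeks that carried floxed Hdac3 alleles, either without Cre (labelled WT) or with Cre driven by Foxn1, a gene of thymic epithelium (labelled HDAC3cKO). HDAC3 is a histone deacetylase that acts in the NCoR and SMRT corepressor complexes. The sorted cells were EpCAM-positive, CD45-negative, low for Ly51 and low for MHC class II, a gate called mTEClo here. About 30000 cells entered each RNA extraction, and for the group labelled HDAC3cKO 10 to 30 mice were typically pooled. Each genotype had 1 array, so no value below has a replicate error and no test between genotypes was possible. Differences are given as the log2 intensity of the array labelled HDAC3cKO minus that of the array labelled WT, with their size as fold, and "higher" and "lower" describe these 2 arrays only. The number of arrays limits the precision. The table gave 34760 probe sets, with a median intensity of 183.2 on the array labelled WT and 177.0 on the array labelled HDAC3cKO. Through a probe set with 1 gene symbol, 19937 genes were named.

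Hdac3 itself was not lower on the array labelled HDAC3cKO. Its log2 level was 10.90 on the array labelled WT and 11.64 on the array labelled HDAC3cKO, a difference of 0.74 or 1.67-fold. That difference lay at percentile 90.4 among 996 genes of like level. A whole-transcript probe set averages over the exons of a gene, and which exons the floxed allele removes is not given in the sources used here, so a probe set that covers exons left in place would not check the deletion. Because this value goes against the genotype label, the arrays are named by their labels throughout, and every direction below rests on those labels. Of 14 measured members of the histone deacetylase and corepressor list, 13 differed by less than 2-fold. Hdac9, a class IIa deacetylase that was below the expression filter, was 2.43-fold lower on the array labelled HDAC3cKO. The median of that list was 0.04, at percentile 51.5 of matched random lists.

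Among 9969 genes above the median expression level, 453 were at least 2-fold higher and 673 at least 2-fold lower on the array labelled HDAC3cKO. Of the 12 named genes with the largest negative differences, 4 are in the fixed list of tuft cells, chemosensory epithelial cells that use the taste signalling cascade, and 1, Klk7, is in the cornified list. Rgs13, a regulator of G protein signalling, was 27.7-fold lower. The taste transduction genes Trpm5, a cation channel, and Gnb3, a G protein beta subunit, were 25.9-fold and 17.0-fold lower. Rgs21, which is found in taste cells, was 23.6-fold lower, Sh2d7 was 21.3-fold lower, Avil, which encodes the actin-binding protein advillin, was 15.1-fold lower, and the bitter taste receptor Tas2r137 was 14.8-fold lower. The beta-defensin Defb6 was 26.5-fold lower, and Myl1, a skeletal muscle myosin light chain, was 25.6-fold lower. Hrnr, a cornified envelope protein, was 21.2-fold lower, Klk7, a protease of the outer epidermis, was 15.9-fold lower, and Clca3b, of a family that includes secreted goblet cell proteins, was 18.5-fold lower.

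The 12 genes with the largest positive differences were of other kinds. The immunoglobulin kappa variable segment Igkv9-120 was 79.1-fold higher on the array labelled HDAC3cKO, from a log2 level of 5.44 to 11.75. The matrix proteins Spon2 and Thbs2 were 14.9-fold and 9.84-fold higher. Gsta3, a glutathione S-transferase, was 14.3-fold higher, and Nqo1, a quinone reductase, was 7.51-fold higher. Upk3b, a uroplakin found in mesothelium, was 8.21-fold higher. The chemokine Ccl2, which recruits monocytes, was 8.13-fold higher. Glrb, a glycine receptor subunit, was 9.69-fold higher, the channel gene Trpm3 was 8.68-fold higher, Dmrta1 was 8.24-fold higher, BC023105 was 8.10-fold higher and Ndrg2 was 7.73-fold higher. Probe sets of gene families with near-identical members, such as Igkv9-120, Gsta3, Clca3b and Tas2r137, can pick up related transcripts, and their values are uncertain for that reason.

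**Figure D1:**
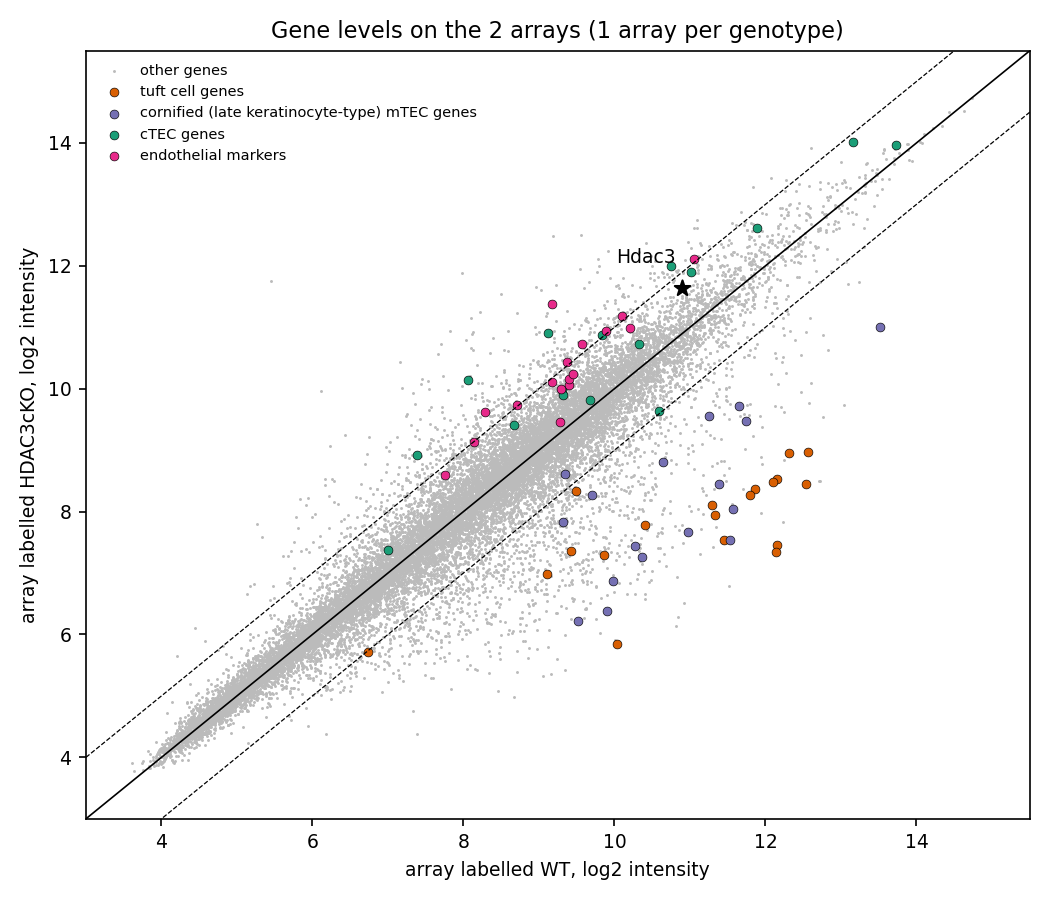
Scatter of log2 intensity on the array labelled WT (x axis) against the array labelled HDAC3cKO (y axis), 1 point per gene, with 4 fixed gene lists in colour, the line of equal level (solid) and the lines of a 2-fold difference (dashed). All 19 tuft cell genes lie on or below the lower dashed line, and all 17 endothelial markers lie above the solid line.

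The first group of comparisons concerned genes of mTEC subsets. All 19 measured tuft cell genes were at least 2-fold lower on the array labelled HDAC3cKO, with a median difference of -3.50 or 11.3-fold. They included Pou2f3, the transcription factor required for tuft cells, which was 11.3-fold lower, and the cytokine Il25, which was 4.17-fold lower. Of 17 cornified genes, 16 were at least 2-fold lower, with a median of -2.83 or 7.10-fold. Krt10, a keratin of suprabasal epidermis, was 11.5-fold lower and the cornified envelope gene Ivl, which encodes involucrin, was 8.67-fold lower. Both medians lay below all 10000 random lists of the same size and expression. Of 11 microfold cell genes, which mark epithelium over lymphoid follicles, 7 were at least 2-fold lower, with a median of -1.24, among them the chemokine Ccl20 at 7.14-fold and the receptor Gp2 at 7.01-fold. Blood cells also express members of this list such as Ccl6, Ccl9 and Spib, and macrophage and dendritic cell markers had a median of -0.88 on the same array. Of 18 ciliated cell genes, 11 were at least 2-fold lower, with a median of -1.13, and 4 of the 18 were above the expression filter. The axonemal dynein Dnah5, itself below the filter, was 5.32-fold lower and Cdhr3 was 5.30-fold lower. Of 13 neuroendocrine genes, 5 were at least 2-fold lower, with a median of -0.92. They were led by Snap25, a protein of vesicle release, at 4.34-fold and the granin Chgb at 4.22-fold, both below the filter. The median of the 5 neuroendocrine genes above the expression filter was -0.36, at percentile 5.4, and did not stand apart. Secretory airway and gland genes went both ways, 8 at least 2-fold lower and 3 at least 2-fold higher of 17, with a median of -0.87 and a mean of -0.53. Bpifa1 and Scgb1a1, secreted airway proteins, were 6.50-fold and 5.95-fold lower. The water channel Aqp5 and the mucin Muc16, the latter below the filter, were 5.49-fold and 5.20-fold higher.

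Genes of mature mTEC were lower as a list. Of 21 measured genes of MHC class II high mTEC, 9 were at least 2-fold lower and none was 2-fold higher, with a median of -0.55 and a mean of -0.85, below all 10000 matched random lists. Dendritic cells also express members of this list such as Cd86, Ctss, Ccl17 and Cd80, and the median of macrophage and dendritic cell markers was -0.88 on the same array. Fezf2, a transcription factor for tissue-restricted antigens, was 7.85-fold lower and the chemokine Ccl17 was 4.005-fold lower. Tnfrsf11a, which encodes the receptor RANK, was 2.19-fold lower. Aire, the other main regulator of tissue-restricted antigens, differed by -0.55 or 1.46-fold. Cd80 differed by -0.85 and Cd40 by -0.41, both costimulatory molecules of mTEC. The class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 differed by between -0.13 and 0.16. H2-DMa differed by 0.51 and the class II transactivator Ciita by -0.50. On the array labelled WT, H2-Aa was at 13.30 and Cd74 at 13.55, although the sort gate was low for MHC class II. Of 20 tissue-restricted antigens, 8 were at least 2-fold lower and 1 was 2-fold higher, with a median of -0.47 and a mean of -1.01, below all 10000 matched random lists. Only 3 of these 20 were above the expression filter, with a median of -2.21. The filter takes the mean of both arrays. On the array labelled HDAC3cKO, Tff3 was at 7.22 and Krt10 at 8.04, so both passed mainly through the other array. The median of these 3 therefore does not show that better expressed antigens differed more. Krt10, which the cornified list also holds, and Mucl2, a salivary protein, were 11.5-fold and 8.33-fold lower. The amine oxidase Maoa was 2.51-fold higher. Mucl2 and Maoa were below the filter. Of 20 genes of TNF receptor and NF-kappaB signalling, which drives mTEC maturation, 1, Tnfrsf11a, was 2-fold lower. The median of that list was -0.20, at percentile 1.72, and neither its mean, at percentile 9.59, nor its median without genes of other lists, at percentile 3.9, stood apart. Relb, the NF-kappaB subunit needed for mTEC, differed by -0.22. The list of genes of MHC class I and antigen processing had a median of -0.06, at percentile 19.8, and none of its 11 members differed by 2-fold.

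Genes of cTEC and of junctional mTEC were higher as lists. Of 16 measured genes of cortical thymic epithelial cells (cTEC), 15 were above 0, 5 were at least 2-fold higher and none was 2-fold lower, with a median of 0.74, above all 10000 matched random lists. Psmb11, the thymoproteasome subunit of cTEC, was 2.90-fold higher, and the serine protease Prss16 was 2.05-fold higher, or 0.96 on the log2 scale and just under 2-fold after loess scaling. Kitl, the ligand of KIT, and the chemokine Cxcl12 were 4.24-fold and 3.47-fold higher. Ly75, a receptor of cTEC, differed by 0.66 and Foxn1, the master regulator of thymic epithelium, by 0.13. The junctional mTEC list holds genes of 1 subset of mTEClo, the CCL21-type cells, and not of the whole sort gate. Ccl21a itself was not analysed. Of its 13 measured genes, 10 were above 0 and 3 below, with a median of 0.40, at percentile 98.7. Of these 13, 3 were at least 2-fold higher and 1 was 2-fold lower. Podoplanin (Pdpn), a marker of junctional mTEC, was 2.74-fold higher and Krt15, a basal keratin, 2.31-fold higher. Krt14 was 2.57-fold lower while its partner keratin Krt5 differed by 0.40, and Trp63, the transcription factor of basal epithelium, by 0.82. The mean of the junctional mTEC list lay at percentile 96.8 and did not stand apart, and its median without genes of other lists was 0.82. Beside these lists, endothelial markers had a median of 0.99 and fibroblast markers of 0.64. Of 23 epithelial adhesion and keratin genes, 8 were at least 2-fold lower, with a median of -0.44, at percentile 0.01, and a mean of -0.67. The tight junction gene Cldn1 was 5.71-fold lower and the epithelial transcription factor Ehf 5.32-fold lower, whereas Epcam, the marker used in the sort, differed by -0.27.

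The Notch pathway, whose receptors and ligands direct cell fate between neighbouring cells, is linked to HDAC3 through the corepressors of its transcription factor RBPJ. Notch1 was 3.13-fold higher on the array labelled HDAC3cKO and its coactivator gene Maml2 3.06-fold higher. The target genes Hey2 and Hey1 were 4.04-fold and 3.62-fold higher. Other members differed less: Jag1 by 0.79, Dll4 by 0.75, Notch3 by 0.57, Hes1 by 0.34, Nrarp by 0.24 and Notch2 by -0.11. Dll3, a divergent ligand that was below the expression filter, was 2.10-fold lower. Of 25 receptors, ligands and pathway components, 2 were at least 2-fold higher and 1 was 2-fold lower, with a median of 0.17, at percentile 91.7. Of 15 target genes, 2 were at least 2-fold higher and none was 2-fold lower, with a median of 0.30, at percentile 97.9, and this list did not stand apart after quantile normalization, at percentile 95.8, after loess, at percentile 96.0, or without genes of other lists, at percentile 96.5. Endothelial markers, with a median of 0.99, were higher on the same array. Pooled RNA does not show which cells the Notch pathway transcripts came from, so a rise within mTEC was not tested.

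**Figure D2:**
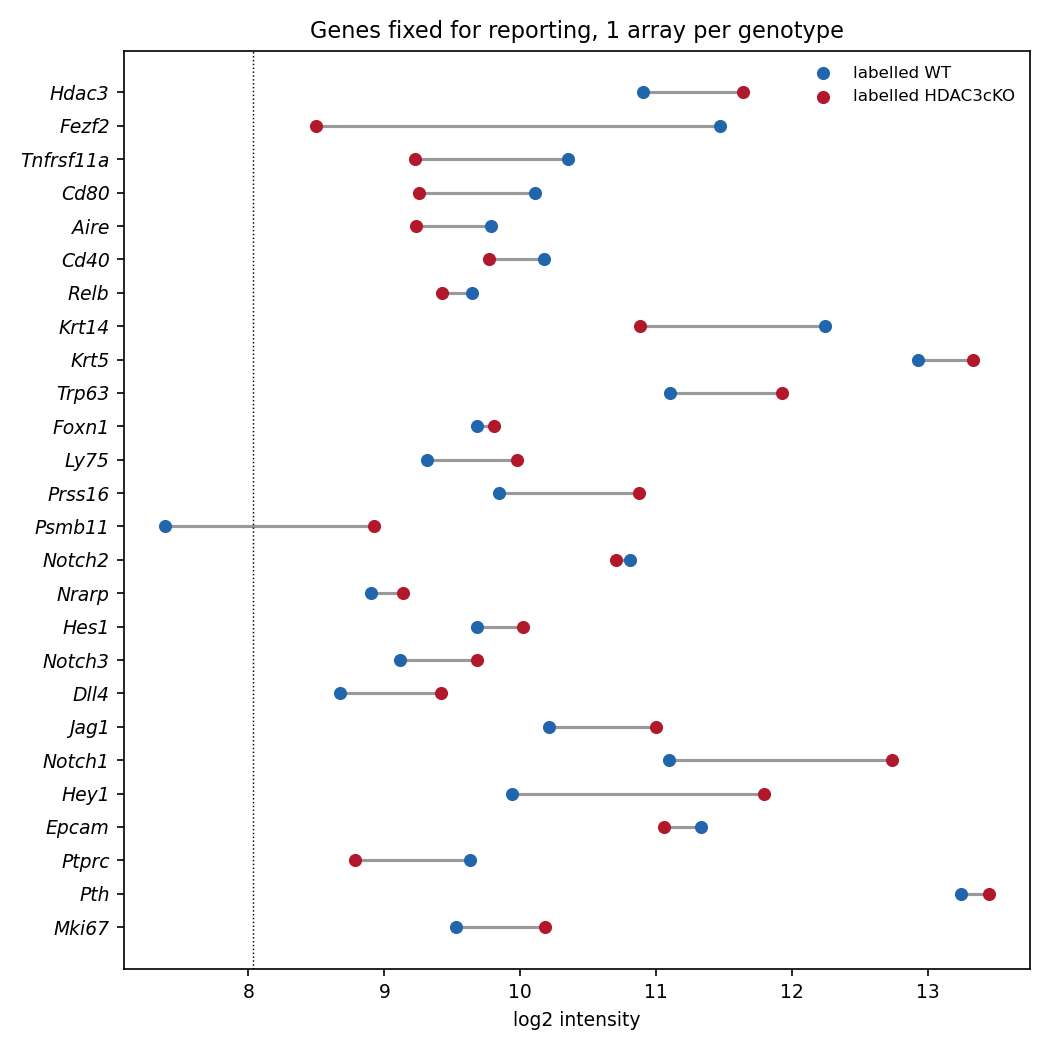
Log2 intensity of 26 genes fixed before the data were examined (x axis) on the array labelled WT (blue) and the array labelled HDAC3cKO (red), joined by a line, with the expression filter of 8.03 as a dotted line. Fezf2 was 11.47 on the array labelled WT and 8.50 on the array labelled HDAC3cKO, and Notch1 was 11.09 and 12.74.

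Cell cycle, p53 target and stress lists were higher as lists, with few members past 2-fold, and the interferon and lipid lists did not stand apart. Of 32 cell cycle genes, 31 were above 0, with a median of 0.53, above all 10000 matched random lists, but only Kif20a, a mitotic kinesin, was 2-fold higher, at 2.65-fold. Mki67, a marker of proliferating cells, differed by 0.66. The p53 target list had a median of 0.40, at percentile 99.8, with 3 of 21 members at least 2-fold higher. Ephx1, an epoxide hydrolase, was 2.97-fold and the sestrin Sesn1 2.67-fold higher. Immediate early and dissociation stress genes had a median of 0.44, at percentile 99.9. In that list Ier3 and Socs3 were 2.44-fold and 2.14-fold higher, and Egr3 and Egr2 were 3.83-fold and 2.07-fold lower. The ribosomal protein list had a median of 0.30, at percentile 98.8, with none of 23 members differing by 2-fold. The median of the interferon-stimulated genes was 0.02, at percentile 36.3, with 3 of 25 members at least 2-fold higher and 3 lower. The chemokine Cxcl10 and the antiviral gene Ifit1 were 2.501-fold and 2.36-fold higher, and the synthetase gene Oas3 and the transcription factor Irf7 were 2.84-fold and 2.39-fold lower. Lipid synthesis and storage genes had a median of 0.05 and a mean of -0.11, at percentile 54.2. Dgat2, an enzyme of triglyceride synthesis, and Me1, malic enzyme, were 4.35-fold and 3.72-fold lower, and the fatty acid transporter Cd36 was 2.37-fold higher. Genes of epithelial-mesenchymal transition had a median of 0.08 and a mean of -0.05, at percentile 65.2. Cdh2, encoding N-cadherin, was 7.70-fold lower, Tgfbi was 3.03-fold lower and Mmp2, a matrix metalloproteinase, was 4.11-fold higher. Thymic stromal cytokines and chemokines had a median of -0.15 and a mean of 0.03, at percentile 2.57, with 6 of 22 at least 2-fold higher, led by Ccl2 and Kitl, and 3 at least 2-fold lower, Ccl20, Il25 and Ccl17.

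Markers of cells outside the sort gate were compared in the same way, since such cells can carry over into a sort. All 17 endothelial markers were above 0 on the array labelled HDAC3cKO and 8 were at least 2-fold higher, with a median of 0.99, above all 10000 matched random lists. The sialomucin Emcn was 4.60-fold higher and Kdr, the VEGF receptor, 2.53-fold higher. Of 20 fibroblast markers, 7 were at least 2-fold higher and none was 2-fold lower, with a median of 0.64, also above all matched random lists, among them the matrix genes Mfap5 at 5.28-fold and Mgp at 2.87-fold. Pericyte and smooth muscle markers had a median of 0.07 and a mean of -0.08, at percentile 64.3. Desmin (Des) was 3.19-fold lower and the kinase gene Mylk 2.11-fold higher. The median of the 7 such markers above the expression filter was -0.83, at percentile 0.09.

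Among blood cell markers, those of macrophages and dendritic cells were the lowest on the array labelled HDAC3cKO. All 22 macrophage and dendritic cell markers were below 0 and 8 were at least 2-fold lower, with a median of -0.88, below all 10000 matched random lists. Lyz1, a lysozyme gene, was 10.6-fold lower and Laptm5, a lysosomal protein of blood cells, 4.24-fold lower. Lyz2, the other lysozyme gene of the list, was 2.12-fold lower. Thymocyte markers had a median of -0.25, at percentile 1.02, with 2 of 21 at least 2-fold lower, the coreceptor Cd4 at 2.39-fold and the chromatin organiser Satb1 at 2.02-fold. Their mean of -0.39, at percentile 2.55, did not stand apart, and the median of the 14 above the expression filter was -0.66. Ptprc, which encodes CD45, the antigen excluded in the sort, differed by -0.84 and was at a log2 level of 9.63 on the array labelled WT. B cell markers had a median of -0.14, at percentile 12.8, with 3 of 14 at least 2-fold lower. They included Fcer2a, itself below the filter, at 4.07-fold and Cd79b at 3.40-fold. The median of the erythroid and platelet markers was 0.07, their mean -0.09 and their percentile 76.4. The platelet chemokine Pf4, itself below the filter, was 2.10-fold lower.

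Marker lists of neighbouring glands and fat did not stand apart. Pth, encoding parathyroid hormone, was at 13.24 on the array labelled WT and 13.45 on the array labelled HDAC3cKO, a difference of 0.20. The parathyroid list had a median of -0.26, at percentile 7.83, and Casr, the calcium-sensing receptor, was 3.24-fold lower. Thyroid markers had a median of -0.14, at percentile 10.97, with the deiodinase Dio1 4.37-fold lower. Adipocyte markers had a median of -0.10 and a mean of 0.05, at percentile 18.6, and none of 9 differed by 2-fold.

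**Figure D3:**
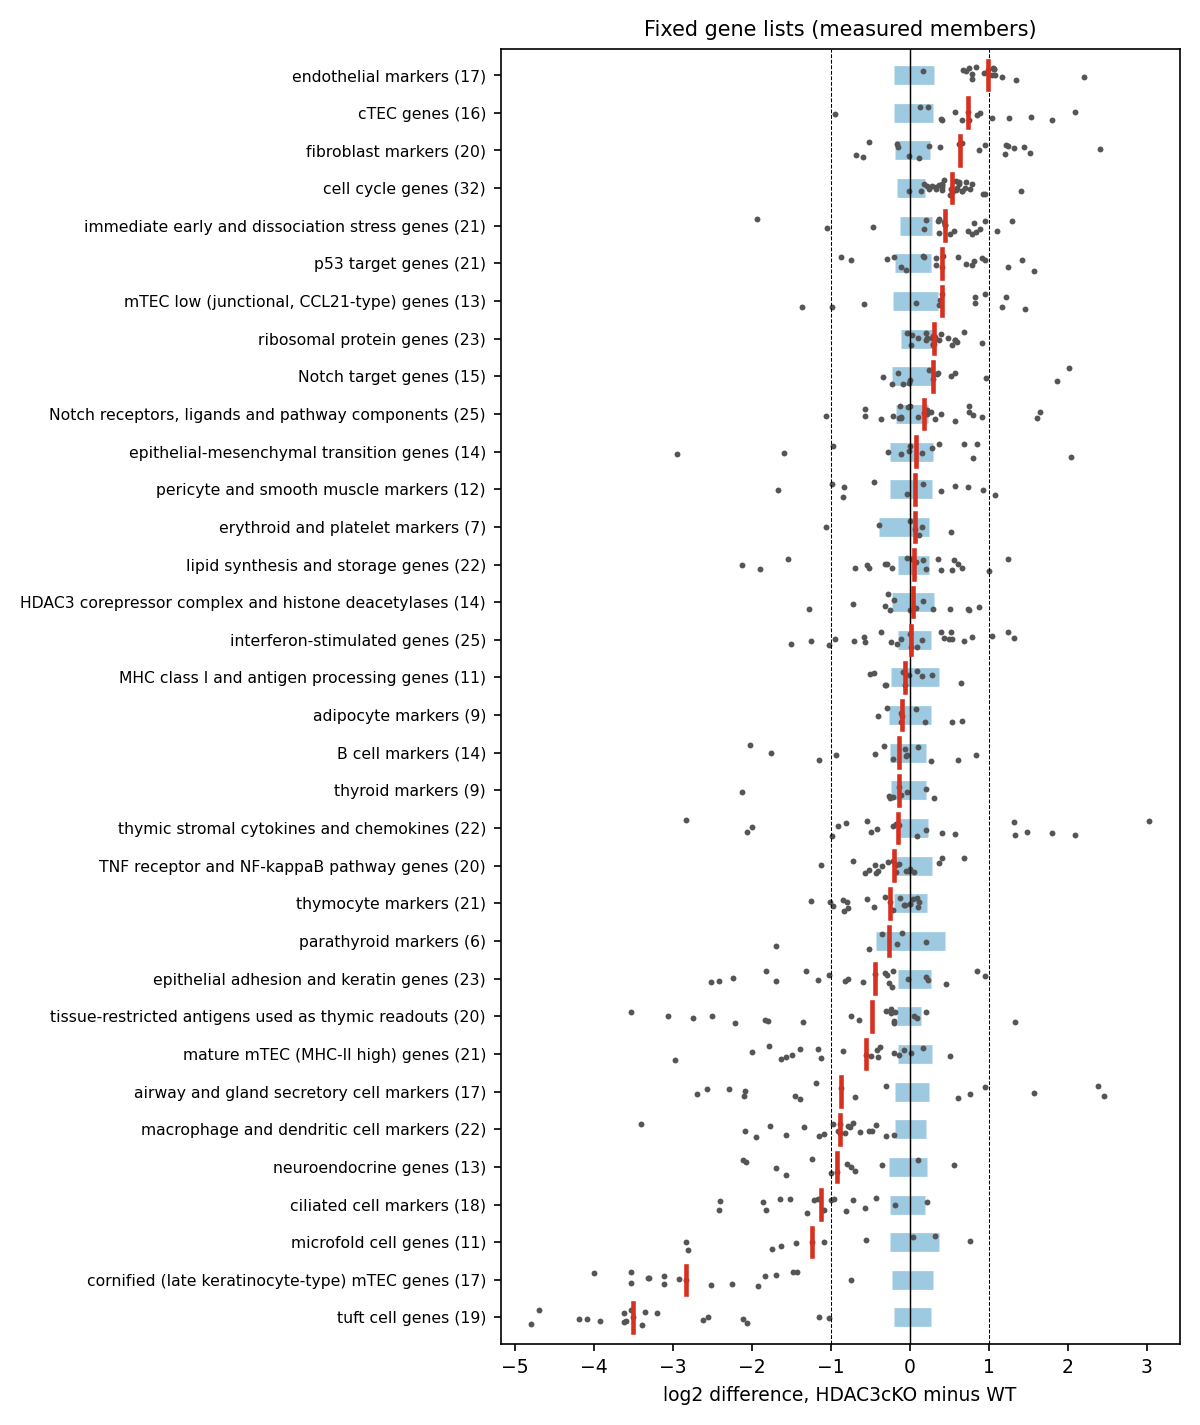
Log2 difference between the array labelled HDAC3cKO and the array labelled WT (x axis) for each measured member (points) of the 34 gene lists fixed before the data were examined, with the number of members in parentheses, the list median (red) and the central 95% of medians of 10000 matched random lists (blue band). The medians run from -3.50 for tuft cell genes to 0.99 for endothelial markers, and 12 lie below and 9 above their band.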

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

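Alternatives were set before the data were examined, except leaving out members shared between lists or, for the NRF2 list, the genes seen before it was written. Each genotype had 1 array, so leaving out an array was not possible. No paired analysis was possible because each genotype had 1 array. The 3 rescalings shifted the median gene difference by at most -0.04, and the counts stayed between 393 and 451 genes higher and between 677 and 715 lower, against 453 and 673 as deposited. The counts moved with the filter and the threshold: 252 higher and 267 lower with a filter at the 75th percentile, 1249 and 1294 at 1.5-fold, 113 and 356 at 3-fold, 1173 lower (593 higher) with no filter, and 710 higher (992 lower) when every probe set was counted. The share of these genes that were higher was 40.2% as deposited, 35.5% after loess, 48.6% at the stricter filter, 49.1% at 1.5-fold and 24.1% at 3-fold. Hdac3 differed by 0.64 to 0.74 under its 4 alternatives. Of 106 other named genes under 4 alternatives each, 1 crossed the 2-fold line, Prss16 at 0.96 after loess. Of 270 list medians or means under alternatives, none changed direction among lists that stood apart, 8 fell inside the central 95% of random lists and 5 fell outside it. Those that fell inside were the junctional mTEC mean of 0.36, the thymocyte mean of -0.39, and neuroendocrine genes above the filter at -0.36. Notch targets fell inside at 0.25 after quantile normalization, 0.20 after loess and 0.30 without shared members. The NF-kappaB list fell inside by its mean of -0.21 and by its median of -0.18 without shared members. Those that fell outside were Notch components at 0.17 against unmatched lists, stromal cytokines at -0.19 after quantile normalization, -0.22 after loess and -0.15 against unmatched lists, and pericyte markers above the filter at -0.83. The cause was not tested. Thyroid and erythroid lists had too few members above the filter for that alternative.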

Other observations

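The tests below were chosen after the results they bear on were seen, except those of the mesothelial, skeletal muscle, and gut and liver lists, whose members and bounds were written before their values were looked up. The bitter taste receptor family was lower almost throughout on the array labelled HDAC3cKO, with 30 of 34 measured Tas2r genes at least 2-fold lower and a median of -2.66, although 9 of the 34 were above the expression filter. Of 12 kallikreins, secreted serine proteases, 7 were at least 2-fold lower, with a median of -1.82 and 5 of the 12 above the filter. Of 24 members of the serpin B clade of protease inhibitors, 8 were at least 2-fold lower, with a median of -0.45 and 9 of the 24 above the expression filter. Of 48 keratins 12 were at least 2-fold lower and 1, Krt15, was higher, with a median of -0.06 and 16 of the 48 above the filter. Defb6 and 1 other of 39 beta-defensins were at least 2-fold lower, with a median of 0.05 and 2 of the 39 above the filter, and of 13 small proline-rich protein genes 5 were at least 2-fold lower, Sprr4 the lowest at -3.02, and 1, Sprr3 at 2.60, was higher, with a median of -0.51 and 4 of the 13 above the filter.

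Some detoxification genes were higher. A list of NRF2 target and glutathione genes, written after Gsta3, Nqo1, Gstm2, Gstm1 and Ephx1 had been seen, had a median of 0.48, at percentile 99.96 of matched random lists, with 5 of 17 at least 2-fold higher. Those 5 are the genes seen before the list was written, so that count restates them. The 12 others had a median of 0.34, at percentile 98.2, and a mean of -0.03, with 2 at least 2-fold lower. Gstm2 and Gstm1 were 5.30-fold and 4.60-fold higher, while Slc7a11, the cystine transporter, and Cbr3 were 4.45-fold and 2.505-fold lower, and Hmox1, Txnrd1 and Srxn1 differed by between -0.18 and 0.22. Plasma cell markers did not move with Igkv9-120. Their median was 0.07, at percentile 67.7, with Jchain 1.79-fold higher and Irf4 3.23-fold lower.

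The first pattern is the low level of tuft cell and cornified genes. Dilution of mTEC RNA by other cells would lower mTEC genes alike. The median of the mature mTEC list lay 2.95 (log2) above that of the tuft list, with its upper quartile at -0.20. That list is of MHC class II high mTEC and dendritic cells also express some of its members, which limits the comparison. The junctional mTEC list, which covers 1 subset of the sort gate, had a median of 0.40 and Epcam differed by -0.27. Neither was lowered alike with the tuft list. A scaling error would move genes of like level alike. Random lists matched to the tuft list on expression had a median of 0.033, but RMA normalizes across arrays and can bring such a median near 0 by itself. That value shows only that tuft genes differed from genes of like level. The low level may extend to other mTEC subtypes that carry peripheral tissue programmes: gut and liver epithelium genes had a median of -1.30, with 9 of 14 at least 2-fold lower and 4 of 14 above the expression filter, whereas skeletal muscle genes had a median of -0.46, with 6 of 20 lower and 3 of 20 above the filter, which does not decide. Fewer such cells and less RNA of these genes per cell cannot be told apart, since 100% of the 36 tuft and cornified values were below 0 and either would give that in pooled RNA.

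The second pattern is a set of mesothelial-type genes that were higher, seen first in Upk3b, Muc16, Lrrn4 at 2.70 and Gpm6a at 2.48. A candidate explanation is mesothelial cells among the sorted cells: 15 measured markers that had not been looked up before had a median of 1.495, above all matched random lists, with 10 at least 2-fold higher, including Upk1b at 2.06 and Wt1 at 1.95. Of these 15, 6 were above the expression filter on the array labelled WT and 11 on the array labelled HDAC3cKO, and Msln, an abundant mesothelial gene that was at 11.13 on the array labelled WT, differed by -0.41, while Calb2 differed by 0.08 and Prg4 by 0.02, and the EpCAM gate would be expected to remove most such cells. The medians of 6 marker lists of other cell types spanned 1.87, from -0.88 for macrophage and dendritic cell to 0.99 for endothelial markers. That span argues only against a lower mTEC share raising all other cell types alike. The gate was set to exclude CD45-positive blood cells, although Ptprc, at 9.63 on the array labelled WT, was above the expression filter. Blood cell lists are part of that span, so a rise of CD45-negative cells alone was not tested. Among lists of CD45-negative cells, pericyte and smooth muscle markers had a median of 0.07, and the 7 of them above the expression filter had a median of -0.83. Release of the mesothelial-type genes within mTEC cannot be told apart from cells of another type in pooled RNA. Both stay open beside the endothelial median of 0.99 and the fibroblast median of 0.64 on the same array. Fibroblasts also express some of the mesothelial markers, such as Gata6 and Efemp1.

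The third pattern is the higher Hdac3 level on the array labelled HDAC3cKO. Exchanged labels cannot be told apart from correct ones, because the only value that bears on them is the Hdac3 difference of 0.74 in which the pattern was seen, and no other value in the tables was tied to the genotype. Signal from exons left in place, or from cells without recombination, would account for a level that was not reduced. It would not by itself account for a higher one, and it was not decided here. Hdac3 was at percentile 97.7 of genes on that array, but levels of different probe sets are not directly comparable. If the labels were exchanged, every direction reported here would be turned.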
